A study of Mus musculus with 12 samples.

How the data were processed

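Gene expression was measured in the white portion of the gastrocnemius, a calf muscle made up mostly of fast fibres, in 12 male C57BL/6 mice aged 17 to 18 weeks that had been fasted overnight. Biotin-labelled total RNA from each mouse was hybridised to 1 Affymetrix MOE430A array, and the settings text of the arrays records a different animal number for each of the 12 arrays. Genotype was taken from the sample titles, which number the 6 transgenic mice 1 to 6 and the 6 wild-type littermates 7 to 12. These numbers name the arrays in the text.

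The authors deposited probe set intensities on a linear scale, 1 column per array, and the submitters' processing notes name RMA, a method that as generally defined corrects probe background, equalises arrays by quantiles and summarises the probes of a set on the log2 scale. No version, probe definition file or further filter is given in the sources used here. The linear scale follows from the values themselves, which were positive throughout, with array medians between 97.81 and 103.1. The deposited per-array settings text, which is classed here as other than expression data, was used only for technical batches. Scanner images and probe-level intensities were not used here, so no probe set could be classed as above or below background. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.0689.

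The intensities were converted to log2 without a pseudocount, the log2 scale being the one on which RMA works. Of the 22690 probe sets in the table, 64 control probe sets were set aside and 22626 were tested. Annotation came from the platform table, in which 20380 of the tested probe sets carried 1 gene symbol, 691 carried several and 1555 were not listed. Probe sets with several symbols or none were tested but not named. Of the named probe sets, 20351 matched a gene in the GRCm38.p6 RefSeq table by Entrez identifier, and no symbol changed. For gene-level results each of 12393 genes was represented by the probe set with the highest mean over all 12 arrays. Disagreement between probe sets of 1 gene is given where a gene is discussed.

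Transgenic and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Fold changes are transgenic over wild type on the log2 scale with limma's standard error, and group levels are means with the SD over 6 arrays. A set of 20 gene lists, covering AMPK, glucose, glycogen, lipid and mitochondrial metabolism, fibre types, signalling, the clock, stress genes and markers of 6 other cell types, was fixed before the data were examined, as were the rule for naming genes and the first set of alternatives. The lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 20 lists. Camera with a correlation estimated from the data and fry were run beside it, and an exact permutation of the list mean over all 924 regroupings of the arrays was added after seeing the data.

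The genes named in the text followed that rule: the AMPK subunit genes, the up to 10 largest increases and 10 largest decreases among genes past the threshold whose level exceeded the median probe set in at least 1 genotype, and the up to 4 members of each list with the smallest p. Other genes are marked as chosen after their values were seen.

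On simulated data built from the measured means and spreads of this comparison over 22626 probe sets, the limma test recovered 38 of 67 probe sets changed by 0.3 on the log2 scale, 62 of 67 changed by 0.5 and 66 of 66 changed by 1, with 9 false calls among 175. The measured data gave 16 calls. With more calls the adjustment accepts larger unadjusted p-values, so these recovery rates may overstate those of the real comparison. A list shifted by 0.1 was found among 12393 simulated genes and none of the other 19 lists was called, but the simulated genes were independent of each other, which real genes are not.

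Hybridization dates in the settings text placed the arrays on 2 days. Runs were inferred here from times that lay close together, which gave 4 runs of 3 arrays. Each day and run held both genotypes. Each run held 2 arrays of 1 genotype and 1 of the other, so run and genotype were partly confounded. Each day held 3 arrays of each genotype. Transgenic replicate 1 and wild-type replicate 7 came from a smaller chip lot and the other 10 arrays from a larger one. These 2 arrays had the lowest mean correlation with the others, 0.9902 and 0.9888 against 0.993 or more, and the highest 3′ minus 5′ signal of the Gapdh control, with a mean of 0.185 on the log2 scale against values between -0.0944 and -0.00174 on the other arrays. Over genotypes this measure of RNA integrity was -0.0108 ± 0.0963 in transgenic and -0.00156 ± 0.0983 in wild-type mice (SD, n = 6 each; exact permutation p = 0.766, two-sided). For the actin control the same measure differed by -0.0545 (transgenic minus wild type; exact permutation p = 0.121, two-sided). No pair of arrays was a duplicate: the closest pair differed by an SD of 0.136 over probe sets, against a median of 0.185 between pairs. The Y-linked gene Kdm5d, between 5.67 and 6.22 on the log2 scale, and Xist, between 6.40 and 7.09, set no array apart from the other males.

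Alternatives covered the scaling between arrays, a filter on dim probe sets, the choice of probe set, the variance prior, array weights and a rank-sum test. Others were blocks for hybridization day, chip lot, run and adjoining animal numbers, each day and the larger lot alone, and leaving out each array in turn. The blocks for lot, run and animal number and the subsets by day and lot were chosen after seeing the data.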

Results

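The study compared skeletal muscle of transgenic mice that carry the R225Q form of the γ3 regulatory subunit of AMPK with muscle of their wild-type littermates. AMPK is a kinase that senses cellular energy, and its γ3 subunit is found mainly in fast-twitch muscle. There were 6 arrays of each genotype, 1 mouse per array, all from the white gastrocnemius of males after an overnight fast. Correlations between arrays on the log2 scale lay between 0.985 and 0.997. The question posed by the design is which transcripts differ between the genotypes under fasting.

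Prkag3, the gene that the transgene encodes, was not analysed here, because no probe set is paired with it in the annotation used, so the genotype labels have no check against the targeted transcript. The subunit genes Prkaa1, Prkaa2 and Prkab2 were likewise not analysed. The other measured AMPK subunits did not pass the test in limma: the log2 fold change was 0.06 ± 0.06 (SE) for Prkab1, 0.05 ± 0.05 for Prkag1 and -0.05 ± 0.06 for Prkag2, each with an adjusted p of 0.999. Leaving out 1 array moved these values to between 0.04 and 0.09 for Prkab1, 0.02 and 0.07 for Prkag1 and -0.08 and -0.02 for Prkag2. Stk11, which encodes the upstream kinase LKB1, was at -0.19 ± 0.05 with an adjusted p of 0.499 over all probe sets in limma, and was the only member of the 5 measured AMPK and upstream kinase genes to pass when adjusted over the list alone (0.0172). As a list these 5 genes did not pass (camera adjusted p = 0.469), with a median of -0.051 on day 1 and 0.035 on day 2.

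Across the transcriptome, 10 probe sets of 8 genes rose in transgenic muscle. Tmem37, which encodes a membrane protein related to calcium channel γ subunits, showed the largest increase, from 8.69 ± 0.24 to 9.71 ± 0.17 log2 units (SD, n = 6 each), a log2 fold change of 1.02 ± 0.10 (SE; limma adjusted p = 0.000512). Gpx3, the secreted glutathione peroxidase, rose from 10.72 ± 0.12 to 11.65 ± 0.22 (log2 fold change 0.93 ± 0.09; limma adjusted p = 0.000512). Rasd2, a small GTPase of the Ras family, rose by 0.61 ± 0.08, and its second probe set gave 0.63 ± 0.10. Ifi30, a lysosomal thiol reductase, rose by 0.55 ± 0.08, Nos1, the neuronal nitric oxide synthase that muscle fibres also express, by 0.47 ± 0.07, and Alas1, the first enzyme of haem synthesis, by 0.35 ± 0.06, with limma adjusted p-values of 0.013, 0.0211 and 0.0286. Each of these 3 calls was lost on leaving out some single arrays, with limma adjusted p-values of up to 0.0511, 0.0723 and 0.109. In each of these genes 6 of 6 transgenic arrays lay above the wild-type mean, which their selection by p makes likely. The other probe set of Nos1 was at 0.12 ± 0.06 and that of Alas1 at 0.17 ± 0.06, neither past the threshold. Il15, a cytokine made by muscle among other tissues, rose by 0.65 ± 0.09 (limma adjusted p = 0.0107); it is dimmer than the naming rule asks for, at 6.44 log2 units in transgenic muscle, and was named after its values were seen.

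Ugp2, the eighth gene, encodes UDP-glucose pyrophosphorylase, which makes the glucosyl donor for glycogen. Its 5 probe sets were all higher in transgenic muscle, with log2 fold changes from 0.30 to 0.47. The brightest was at 0.30 ± 0.05 with a limma adjusted p of 0.0511, just outside the threshold, and 2 others passed, at 0.47 ± 0.07 and 0.45 ± 0.08 (limma adjusted p = 0.0245 and 0.0409).

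In the other direction, 6 probe sets fell, and 5 of them carry a gene name. Gdap1, an outer mitochondrial membrane protein, fell from 7.18 ± 0.29 to 6.31 ± 0.29 log2 units (SD, n = 6 each), a log2 fold change of -0.87 ± 0.14 (SE; limma adjusted p = 0.0281). Its other probe sets were at -0.50, -0.30 and -0.03. Tmem100, a transmembrane protein, fell by 0.71 ± 0.12, Tppp3, a tubulin-binding protein, by 0.35 ± 0.05, and Ppp1r14b, an inhibitor of protein phosphatase 1, by 0.29 ± 0.05, with limma adjusted p-values of 0.0285, 0.0257 and 0.0409. On leaving out 1 array the limma adjusted p rose to as much as 0.106 for Gdap1, 0.109 for Tmem100, 0.0763 for Tppp3 and 0.151 for Ppp1r14b. The other probe set of Ppp1r14b was at 0.09 ± 0.08. Myl4, the atrial and embryonic myosin light chain, was named after its values were seen: 1 probe set fell by 0.52 ± 0.08 (limma adjusted p = 0.0281), while its brighter probe set was at 0.04 ± 0.07 and did not pass. The remaining probe set is unnamed here and fell by 0.66 ± 0.08 (limma adjusted p = 0.00146).

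**Figure D1:**
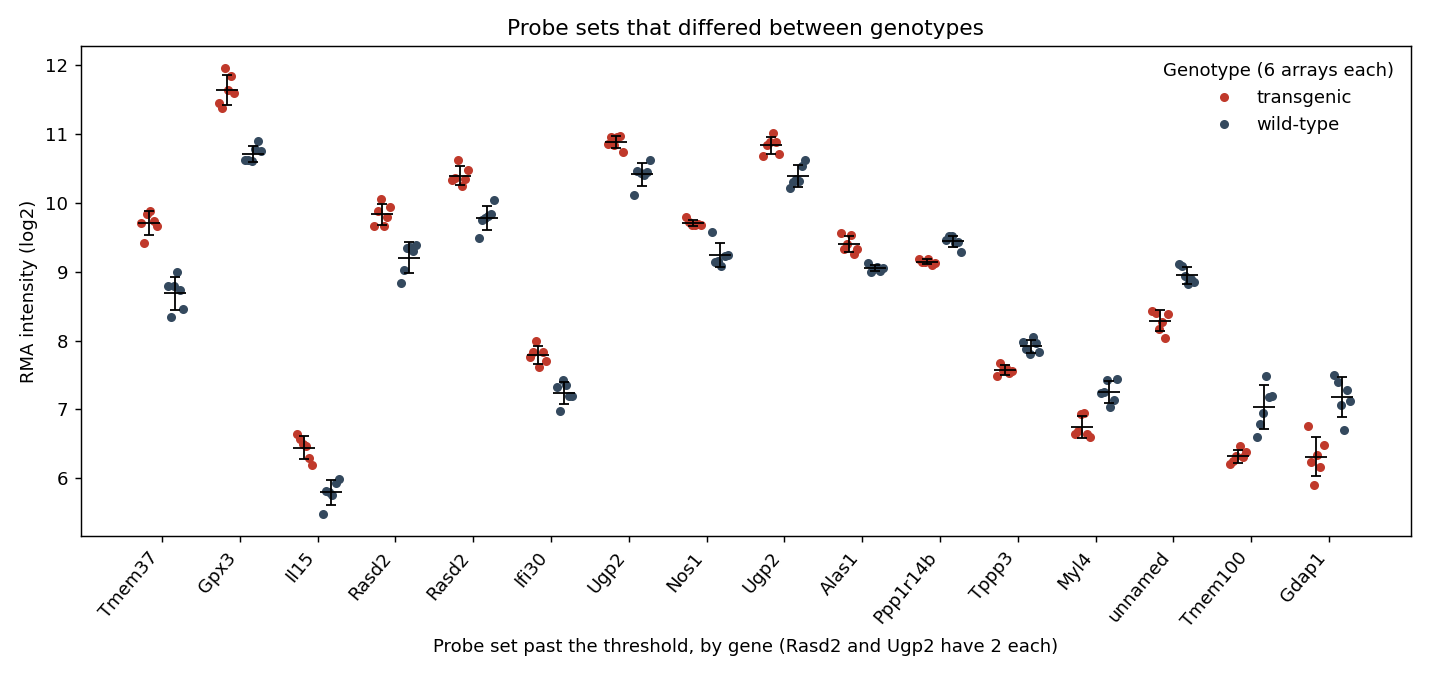
Log2 RMA intensity (vertical axis) of the 16 probe sets past the threshold, by gene, with 1 point per array, horizontal marks for group means and bars for the SD (n = 6 per genotype). The genotypes do not overlap in 15 of the 16 probe sets, and Tmem37 shows the largest increase.

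The genotypes did not overlap in 15 of these 16 probe sets, the exception being that of Gdap1. Over all 22626 probe sets they did not overlap in 0.504%, where chance gives 0.216%. An unadjusted p under 0.05 was found for 1047 probe sets, against 1131 by chance, and the central 90% of log2 fold changes lay between -0.125 and 0.121. With hybridization day as a block 12 probe sets rose and 11 fell, including all 16. The days hold both genotypes equally, so this block alters only the spread. Within each day, with 3 arrays per genotype, 1 rose and 0 fell on day 1, none of them among the 16, and 1 rose and 1 fell on day 2, both among the 16 (937 and 882 probe sets at an unadjusted p under 0.05 in limma). The 16 probe sets had the direction of the full comparison on each day, which for the 15 without overlap follows from the separation itself. Without the 2 arrays of the smaller chip lot, a check added after seeing the data, 14 rose and 6 fell, and 13 of the 16 were among them. With hybridization run as a block, also added afterwards, 4 rose and 2 fell, all 6 of them among the 16. The runs held the genotypes unequally, so this block also alters the fold changes. Leaving out 1 array gave between 4 and 12 higher and between 1 and 6 lower, and among the genes named by the rule Tmem37, Gpx3 and Rasd2 passed whichever array was left out.

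The glycogen list, asked about because AMPK acts on glycogen stores, did not pass as a group: 12 of its 19 measured members had positive fold changes, with a median of 0.05, and the camera adjusted p was 0.0708. The median was 0.105 on day 1, 0.013 on day 2 and 0.013 within the larger chip lot. The list passed in the higher direction without transgenic replicate 1 (camera adjusted p = 0.0207) or 5 (0.0429) or wild-type replicate 8 (0.044), 11 (0.0269) or 12 (0.00858), and with adjoining animal numbers as a block (0.0395). These passes were at the preset correlation. Over all arrays the camera adjusted p was 0.404 with an estimated correlation, the fry adjusted p 0.489 and the exact permutation p of the list mean 0.123. None of its representative probe sets passed over all probe sets, and 2 passed adjusted over the list alone, Ugp2 and Gbe1. Gbe1, the glycogen branching enzyme, was at 0.48 ± 0.13 and Stbd1, a glycogen-binding protein, at 0.26 ± 0.10. Gys1, the muscle glycogen synthase, was at 0.15 ± 0.06. Each was above the wild-type mean in 6 of 6 transgenic arrays. Members named for a small p tend to be so, which makes this no separate support. Glucose uptake and glycolysis genes were balanced, with 10 of 19 positive and a camera adjusted p of 0.654. Their median of 0.02 and mean of -0.02 differ in sign. The glucose transporter gene Slc2a3 was the one member past the threshold adjusted over the list alone, at -0.50 ± 0.10 (adjusted p over all probe sets 0.132 in limma), and Pkm, the pyruvate kinase of muscle, was at 0.07 ± 0.05.

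Neither list of lipid metabolism genes passed over all arrays. Lipogenesis and triglyceride synthesis genes had 7 positive and 8 negative values (camera adjusted p = 0.654), with a median of 0.167 on day 1 and -0.117 on day 2, where the list passed in the lower direction (camera adjusted p = 0.00193). On day 2 the adipocyte markers had a median of -0.263, against -0.094 on day 1. Srebf1, a transcription factor of lipogenesis, was at -0.37 ± 0.08 and was the only member past the threshold adjusted over the list alone (limma adjusted p over all probe sets 0.132), while Thrsp was at 0.32 ± 0.11, Lpin1 at 0.26 ± 0.09 and Mlxipl at 0.13 ± 0.05. Fatty acid uptake and β-oxidation genes had 14 positive and 13 negative values with a camera adjusted p of 0.71, a median of 0.00031 and a mean of -0.0091, and none passed over all probe sets or adjusted over the list alone. The list median was -0.042 on day 1 and 0.044 on day 2. In the lower direction the list passed on day 1 alone (camera adjusted p = 0.0434) and without transgenic replicate 4 (0.0161). With an estimated correlation over all arrays the camera adjusted p was 0.945 for fatty acid and 0.751 for lipogenesis genes. Among the fatty acid genes Etfb was at -0.16 ± 0.06, Lpl, the lipoprotein lipase, at -0.22 ± 0.13, and Cpt2, a carnitine palmitoyltransferase, at 0.10 ± 0.07 (0.06 without transgenic replicate 4). The metabolic transcription regulators had 11 positive and 16 negative values (camera adjusted p = 0.654), with Nrip1, a nuclear receptor corepressor, at -0.35 ± 0.11 and Nr4a1 at 0.20 ± 0.07, and again no member passed either way.

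Oxidative phosphorylation genes were higher together by a small amount. Of 64 measured members, 60 had positive fold changes, with a median log2 fold change of 0.08 (camera adjusted p = 4.44e-16). The adjusted p was 0.159 with an estimated correlation, and the exact permutation p of the list mean was 0.0108 (0.108 adjusted over the 20 lists). No single member passed over all probe sets or adjusted over the list alone. The 4 with the smallest p were Cox8b at 0.19 ± 0.05, Atp5g1 at 0.21 ± 0.06, Uqcrq at 0.20 ± 0.06 and Ndufb5 at 0.19 ± 0.06, which belong to 4 different respiratory complexes. Pyruvate dehydrogenase and tricarboxylic acid cycle genes had 21 of 26 positive values with a median of 0.08 (camera adjusted p = 6.16e-06). For this list the adjusted p was 0.236 with an estimated correlation. Mdh1, a malate dehydrogenase, was at 0.22 ± 0.07 and Dlat, a subunit of pyruvate dehydrogenase, at 0.22 ± 0.10 (0.13 without wild-type replicate 7); no member passed over all probe sets or adjusted over the list alone. Its median was 0.106 on day 1, 0.042 on day 2 and 0.044 within the larger chip lot, where the camera adjusted p was 0.00129, and wild-type replicate 7 of the smaller lot had a list mean of 10.3 log2 units against 10.4 to 10.5 in the other wild-type arrays. The median of the oxidative phosphorylation list was 0.096 on day 1, 0.054 on day 2 and 0.066 within the larger lot.

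Genes of slow and oxidative fibres were lower in transgenic muscle, with 13 of 16 negative and a median of -0.35 (camera adjusted p = 0.000208). The adjusted p was 0.404 with an estimated correlation and the exact permutation p of the list mean was 0.16. The list mean was 8.59 ± 0.28 log2 units in transgenic and 8.89 ± 0.38 in wild-type muscle (SD, n = 6 each). The slow calcium pump gene Atp2a2 was at -0.52 ± 0.23, the slow myosin heavy chain Myh7 at -0.51 ± 0.26 and Myh2, the heavy chain of type IIA fibres, at -0.35 ± 0.17, none past the threshold over all probe sets or adjusted over the list alone. Without wild-type replicate 9, Atp2a2 was at -0.34 and Myh7 at -0.30, and without transgenic replicate 6 Myh2 was at -0.23. The list median was -0.57 on day 1, -0.115 on day 2 and -0.362 within the larger chip lot. Fast glycolytic fibre genes did not pass (median -0.0034, 6 positive and 7 negative, camera adjusted p = 0.572): Myh4, the heavy chain of type IIB fibres, was at 0.03 ± 0.06 (-0.01 without wild-type replicate 7) and Pvalb, parvalbumin, at -0.02 ± 0.05 (-0.0007 to -0.0458 on leaving out 1 array), and no member passed over all probe sets or adjusted over the list alone.

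The lists for insulin signalling, protein breakdown and autophagy, and the circadian clock did not pass, with camera adjusted p-values of 0.405, 0.488 and 0.0708. Grb14, an adaptor of the insulin receptor, was at 0.40 ± 0.19 (0.24 without transgenic replicate 1), Akt1 at 0.14 ± 0.06, Ulk2 at -0.20 ± 0.09 and the clock gene Nr1d2 at -0.16 ± 0.08; no member of the 3 lists passed over all probe sets or adjusted over the list alone. Clock genes had 11 of 16 negative values, with a median of -0.05 (-0.043 on day 1 and -0.050 on day 2), and passed in the lower direction without transgenic replicate 4 (camera adjusted p = 0.0193) or 6 (0.0302) or wild-type replicate 7 (0.041) or 8 (0.0123). Over all 12 arrays they passed with the mean over each gene's probe sets (0.0202) and with run (0.0387) or adjoining animal numbers (0.0471) as a block. Protein breakdown genes passed in the higher direction without transgenic replicate 1 (0.00854) or wild-type replicate 10 (0.0122). With an estimated correlation over all arrays the camera adjusted p was 0.318 for clock and 0.845 for protein breakdown genes. The exact permutation p of the list mean was 0.225 and 0.69.

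The list of immediate early and heat shock genes, which respond to acute stimuli, was higher in transgenic muscle, with 14 of 19 positive and a median of 0.24 (camera adjusted p = 1.06e-06). Its heat shock members, named after their values were seen, showed no clear rise. Hspa1a was at -0.09, Hspa1b at -0.05, Hsph1 at -0.01, Hspb1 at 0.04, Dnajb1 at 0.06 and Cryab at 0.12. The shift thus lay in immediate early members, though Jun (-0.07) and Myc (-0.16) were negative. The adjusted p was 0.236 with an estimated correlation, and the exact permutation p of the list mean was 0.0433 (0.199 adjusted over the lists). Egr1 was at 1.24 ± 0.36, Btg2 at 0.82 ± 0.25, Junb at 0.64 ± 0.23 and Zfp36 at 0.58 ± 0.20. None of them passed over all probe sets, and Egr1 and Btg2 passed adjusted over the list alone. The list median was 0.327 on day 1 and 0.15 on day 2. The arrays of the smaller chip lot held the highest list mean, 8.47 log2 units in transgenic replicate 1, and the lowest, 7.46 in wild-type replicate 7. Without them the median was 0.141 (camera adjusted p = 0.0034).

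Among markers of other cell types, endothelial genes were higher in transgenic muscle. Of the 12 members 11 were positive with a median of 0.14 (camera adjusted p = 2.99e-08), and this list alone kept its call with an estimated correlation, at an adjusted p of 0.0458. The list mean was 7.96 ± 0.06 against 7.83 ± 0.06 log2 units (SD, n = 6 each; exact permutation p = 0.00433, two-sided, 0.0866 adjusted over the 20 lists). No member passed over all probe sets and 6 passed adjusted over the list alone. Cdh5, the cadherin of endothelial junctions, was at 0.28 ± 0.08, Esam at 0.19 ± 0.06, Emcn at 0.19 ± 0.06 and Kdr, the main receptor for VEGF, at 0.19 ± 0.07. The list median was 0.199 on day 1 and 0.101 on day 2.

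Adipocyte markers were lower, with 7 of 7 negative and a median of -0.09 (camera adjusted p = 0.000258). The adjusted p was 0.236 with an estimated correlation. None passed over all probe sets, and 3 passed adjusted over the list alone: Adipoq, which encodes adiponectin, at -1.01 ± 0.37, Lep, leptin, at -0.52 ± 0.15 and Cidec, a lipid droplet protein, at -0.52 ± 0.18. Adipoq was at -0.16 on day 1 and -1.85 on day 2, and at -0.65 without transgenic replicate 5. On day 1 alone the camera adjusted p of the list was 0.427. Fibroblast and extracellular matrix genes had 15 of 17 negative values with a median of -0.11 (camera adjusted p = 0.000258). The adjusted p was 0.404 with an estimated correlation, and the day 1 median was 0.004 against -0.161 on day 2. Postn, the matrix protein periostin, was at -0.16 ± 0.06 and Sparc at -0.14 ± 0.08 (-0.09 without wild-type replicate 12), and no member passed over all probe sets or adjusted over the list alone. Immune cell markers (9 of 16 positive, camera adjusted p = 0.359), blood cell markers (2 of 5 positive, 0.979) and Schwann cell markers (5 of 6 positive, 0.105) did not pass, and no member of these 3 lists passed over all probe sets or adjusted over the list alone. On day 1 alone the immune (camera adjusted p = 0.00356) and Schwann cell lists (0.0211) passed in the higher direction, and on day 2 alone the blood cell list (0.0434) in the lower. The immune list also passed without wild-type replicate 12 (0.0268), and the Schwann cell list without transgenic replicate 3 (0.0435) or 4 (0.0169) or wild-type replicate 12 (0.0268). Over all 12 arrays the Schwann cell list passed with the filter on dim probe sets (0.0399) and with run as a block (0.0278). With an estimated correlation the camera adjusted p was 0.712 for the immune, 0.984 for the blood cell and 0.464 for the Schwann cell list. The blood cell median of -0.0061 and mean of 0.034 differ in sign.

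**Figure D2:**
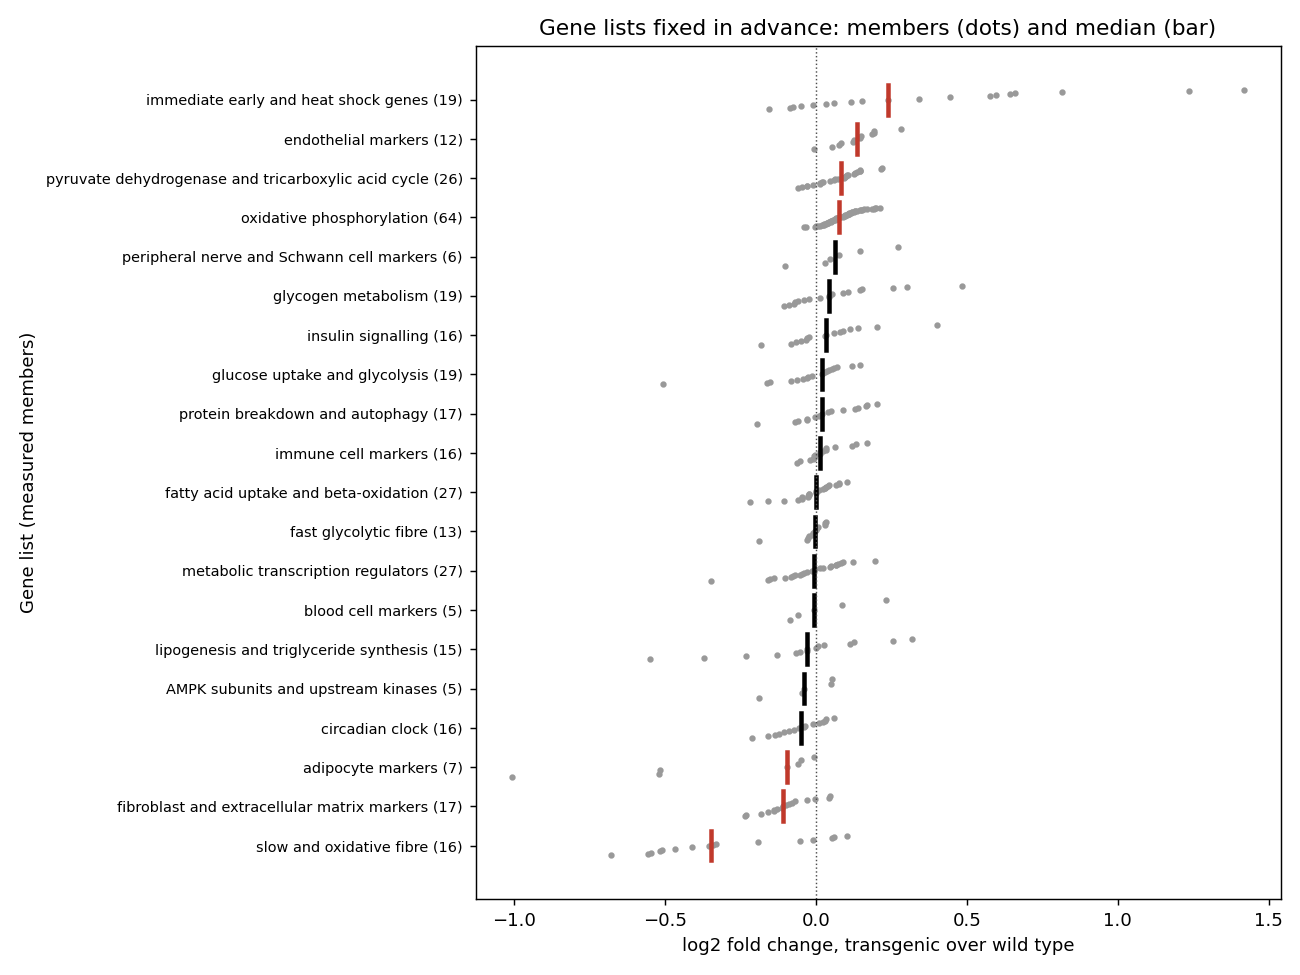
Log2 fold change, transgenic over wild type (horizontal axis), of the members (dots) of the 20 gene lists (vertical axis, with the number measured), with bars at list medians, red where the camera adjusted p at the preset correlation was under 0.05. Members of the slow-fibre list have a median of -0.35 and members of the oxidative phosphorylation list a narrow range around 0.08.

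**Figure D3:**
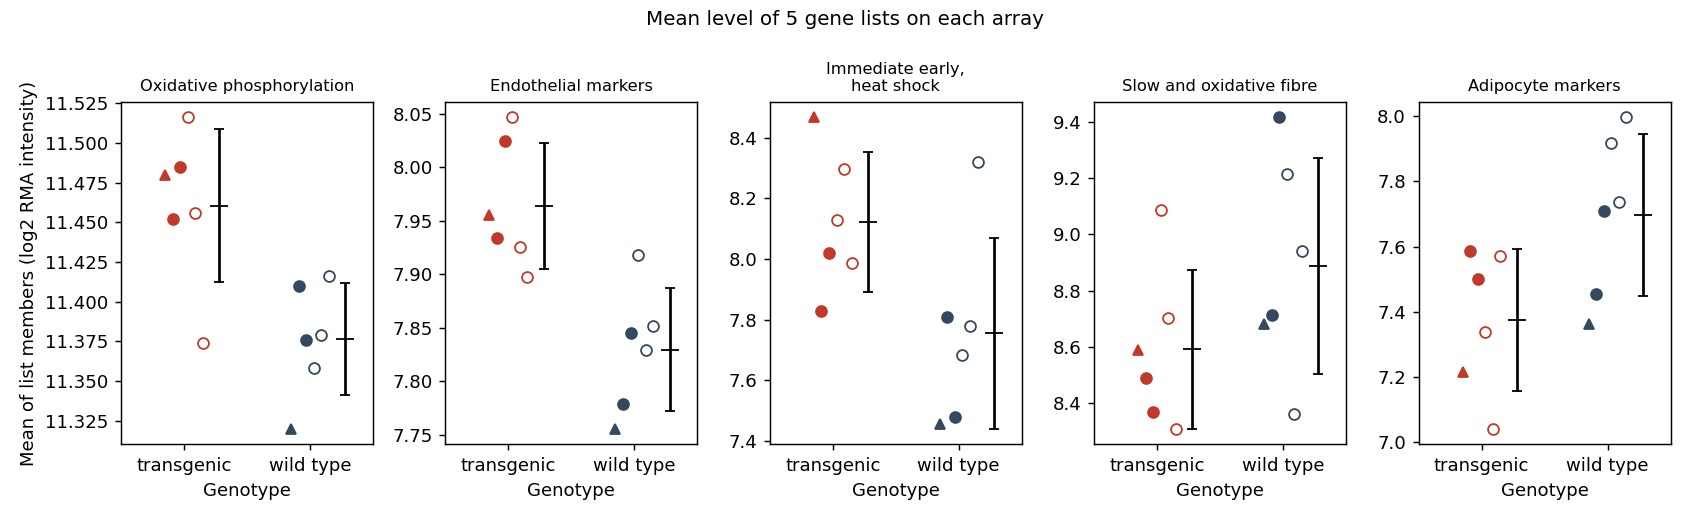
Mean log2 RMA intensity of the members of 5 lists (vertical axes, which do not start at 0) on each array, by genotype; triangles mark the smaller chip lot, filled symbols day 1, open symbols day 2, and bars the mean and SD (n = 6). The slow-fibre means overlap widely between genotypes, while the endothelial means differ by more than their SD of 0.06.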

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

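The tests of the chip lot, the exact permutation test of the slow-fibre list, the comparison of endothelial with fibroblast genes and the choice of chromosome 8 were made after the results were seen. The other tests in this part were written down before their outcome.

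The first pattern is the 16 probe sets that passed between the genotypes. Of 100 drawn splits of the 12 arrays into 6 and 6, only the real split (1 of 100) gave as many probe sets, and the highest of the others gave 5. This makes chance an unlikely source of the number but does not exclude it, since 1 of 100 is the smallest share these draws can give. Each chip lot held the genotypes in equal number, and within the larger lot alone the median ratio of the log2 fold change to that over all arrays was 0.994 (range 0.843 to 1.1). In that lot 13 of the 16 were past the threshold, so most calls did not need the 2 arrays of the smaller lot. The ratio is a weak test, because the larger lot holds 10 of the same 12 arrays and the genotypes did not overlap in 15 of the 16 probe sets. With the mean level of the slow-fibre genes as a covariate, the median ratio of new to old log2 fold change was 1.02 (range 0.903 to 1.1). This too is a weak test of a varying share of slow-fibre muscle in the dissected piece. The slow-fibre means overlapped widely between genotypes while 15 of the 16 probe sets did not overlap, so the covariate could hardly lower their fold changes. With this covariate 8 of the 16 passed, since the median standard error went from 0.0804 to 0.0904 while the median size of the fold change went from 0.581 to 0.579, and the transgene itself remains an open, untested explanation.

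The second pattern is that 4 of the 11 genes called by their representative probe set lie on chromosome 8: Ifi30, Rasd2, Il15 and Tppp3. Random draws gave 0.57 on average, and the permutation p for so many on any chromosome was 0.0147, while among the wider set of 40 genes with an unadjusted p under 0.001 in limma 7 lay there against 2.1 expected (permutation p = 0.0521). A candidate explanation is a chromosomal segment from another strain, linked to the transgene, as the mice are of generation F5: of the 201 other measured genes between these 4, 7.96% had an unadjusted p under 0.05 in limma, against a median of 4.48% and a 95th percentile of 7.96% in equally long windows elsewhere, so a segment and gene regulation cannot be told apart. Of the 11 called genes 0 had another within 10 measured genes (0.17 expected), but this window was too narrow a test, because even the closest of the 4, Rasd2 and Il15, are the genes at positions 314 and 326 of the 646 measured on the chromosome. The insertion site is not given in the sources used here. These counts leave out Ugp2 and Myl4, whose called probe sets are not the representative ones. Among the 11, Gpx3 and Tmem100 lie on chromosome 11 and Gdap1 and Tmem37 on chromosome 1. A gathering on chromosome 8 alone is thus not established for all called genes.

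The third pattern is the 7 gene lists past the camera threshold. Among the 100 drawn splits 26 gave at least as many lists, the highest of the others 11, so chance is not excluded for their number. The slow-fibre genes, with an exact permutation p of 0.16, a genotype difference of -0.296 and an SD of 0.337 within genotypes, may reflect a share of slow-fibre muscle that varies between dissected pieces in both genotypes. The same variation is an unlikely source of the oxidative phosphorylation shift, whose median was 0.0922 with the slow-fibre covariate and 0.0768 without. For the endothelial genes over all arrays, the fibroblast upper quartile of -0.07 lay below the endothelial lower quartile of 0.0831. This argues against a lower share of muscle RNA that raises all other cell types alike. On day 1 alone the endothelial median was 0.199, the immune 0.113, the Schwann cell 0.126 and the blood cell 0.0702. The fibroblast median was 0.00392 and the adipocyte median -0.0943 on that day, so a rise shared by some cell types is not settled. The endothelial median of 0.141 within the larger chip lot argues against the arrays of the smaller lot as the source of its shift. By contrast, going from all arrays to the larger lot moved the median from 0.0847 to 0.0436 for pyruvate dehydrogenase and tricarboxylic acid cycle genes. For immediate early and heat shock genes it went from 0.238 to 0.141.

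Single arrays stood apart from the other 5 of their genotype in 19 of the 224 groups of 6 values examined (8.48%), where chance gives about 1 in 20. Wild-type replicate 7 held 9 of the 19 and transgenic replicates 1 and 5 held 3 each. Both arrays of the smaller chip lot stood apart in the 3′ minus 5′ signal of Gapdh, at 0.184 in wild-type replicate 7 and 0.185 in transgenic replicate 1, and in mean correlation with the other arrays, at 0.989 and 0.99. Nos1 was at 9.57 log2 units in wild-type replicate 7, with the others between 9.08 and 9.24, and at 9.8 in transgenic replicate 1, with the others between 9.68 and 9.72. In wild-type replicate 7, Myh4 was at 13.2 (others 13.5), Ulk2 at 8.31 (8.64 to 8.78), Postn at 6.02 (6.21 to 6.3) and S100b at 6.31 (5.96 to 6.09). The list means of that array were 10.3 for pyruvate dehydrogenase and tricarboxylic acid cycle genes (10.4 to 10.5) and 13.1 for fast-fibre genes (13.2 to 13.3). In transgenic replicate 5, Adipoq was at 6.6 (8.38 to 9.17), Mef2c at 10.9 (11.3 to 11.4) and Actn3 at 13.6 (13.7). Atp2a2 was at 9.73 in transgenic replicate 4 (8.77 to 9.11), and Slc4a1 at 6.78 in transgenic replicate 3 (5.9 to 6.14). Myh2 was at 11.2 in wild-type replicate 11 (11.7 to 12), and Pdha1 at 11.9 in wild-type replicate 8, with the others near 12.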

How the results depend on the processing

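The blocks for chip lot, run and animal number, the subsets by day and lot and the exact permutation of list means were chosen after seeing the data. Against 10 probe sets higher and 6 lower, equalized array medians, repeated quantile normalization, a filter on dim probe sets, 1 probe set per gene and a trended robust prior kept both counts within 1.5 times, and the 16 probe sets kept their direction wherever they were tested. Array weights gave 16 higher and 25 lower, a hybridization day block 12 and 11 and a chip lot block 20 and 14, each including all 16. Days and lots hold both genotypes equally, so these blocks leave fold changes as they are and alter only the spread. The exact rank-sum test gave 0 and 0, with 1055 probe sets at an unadjusted p under 0.05 and 114 at the smallest possible p of 0.00216, too few to pass after adjustment over 22626 probe sets. A run block gave 4 and 2, with fewer degrees of freedom and with altered fold changes, as runs hold the genotypes unequally. Day 1 alone gave 1 and 0 (none of the 16) and day 2 alone 1 and 1 (both of the 16), with fewer arrays. Leaving out 1 array gave 4 to 12 higher and 1 to 6 lower. The higher count moved by over 1.5 times without transgenic replicates 2 (4), 3 (5) and 5 (6) and wild-type replicates 8 (5), 9 (6) and 11 (4), and the lower count without transgenic replicates 2, 3 and 5 (2 each), 4 (3) and 6 (1) and wild-type replicates 7, 8 and 9 (2 each), 11 (1) and 12 (3).

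Array labels share no replicate number between genotypes and so pair no arrays. Settings text gives adjoining animal numbers in 6 pairs, whose deviations from the group means correlated at 0.46, 0.19, -0.011, -0.35, 0.21 and 0.17. The 0.46 belongs to transgenic replicate 1 and wild-type replicate 7, the 2 arrays of the smaller chip lot. For that pair, animal numbers and lot cannot be told apart. In 2 of 6 pairs the transgenic array correlated best with its partner among the wild-type arrays, and the reverse was not examined. With these pairs as a block 11 probe sets were higher and 14 lower, and 13 of the 16 were among them.

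Of 20 lists 4 were higher and 3 lower, and camera with an estimated correlation and fry each gave 1 and 0, the endothelial list. In the order pyruvate dehydrogenase and tricarboxylic acid cycle, oxidative phosphorylation, slow fibre, immediate early, adipocyte and fibroblast, the adjusted p was 0.236, 0.159, 0.404, 0.236, 0.236 and 0.404 with an estimated correlation, 0.266, 0.0614, 0.489, 0.349, 0.266 and 0.489 by fry, and 0.199, 0.108, 0.371, 0.199, 0.199 and 0.402 by exact permutation, which gave 0.0866 for the endothelial list. These 3 tests allow for correlation between genes. On day 1 alone the camera adjusted p was 0.427 for adipocyte genes and 0.891 for fibroblast genes, whose direction was reversed, and on day 2 alone 0.214 for slow-fibre genes; the cause was not tested. Leaving out 1 array gave 4 to 7 lists higher (7 without wild-type replicate 12) and 3 to 5 lower (5 without transgenic replicate 4). Across named genes and alternatives, 2059 values stayed on their side of the threshold, 89 lost it and 12 gained it. Most of the 2059 belong to genes that had not passed. Of 24 alternatives, Gpx3 kept its call in 23, Rasd2 and Tmem37 in 22 each and Ifi30 in 20. Tmem100 kept it in 14, Nos1 in 13, Alas1, Gdap1 and Tppp3 in 11 each and Ppp1r14b in 4. The sign changed in 13 of the 2059, in 11 genes that did not pass (Myh4, Slc4a1, Alas2, Bpgm, Dpt, Grb10, Ldhb, Lyz2, Mef2c, Mrc1 and Prkab1), 10 of them within a single day. Leaving out 1 array ended the call of Ifi30 without transgenic replicate 2 or wild-type replicate 11 and those of Nos1, Alas1, Gdap1, Tmem100, Tppp3 and Ppp1r14b without several arrays. Lists outside the threshold passed it in 27 cases, among them glycogen genes without wild-type replicate 12 (camera adjusted p = 0.00858) and clock genes without wild-type replicate 8 (0.0123). None of these cases was with an estimated correlation or by fry. Without background values, no limit from dim signal could be set.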

Other observations

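The group below was chosen after its members were seen among the smallest p-values, and all its tests were made afterwards. Genes of cytosolic ribosomal proteins, which build the ribosome of the cytoplasm, were lower as a group in transgenic muscle. Of 47 measured genes, paralogs included, 43 had negative log2 fold changes, with a median of -0.10, and the list mean was 10.09 ± 0.04 log2 units against 10.19 ± 0.05 in wild-type muscle (SD, n = 6 each; exact permutation p = 0.00649, two-sided). None passed over all probe sets, while 19 had an unadjusted p under 0.05 in limma in the lower direction and 0 in the higher. In the same comparison 15 of 17 fibroblast and matrix markers (median -0.108) and 7 of 7 adipocyte markers (median -0.0946) were also negative. Rps3a1 was at -0.27 ± 0.05, Rps4x at -0.20 ± 0.06 and Rps28 at -0.19 ± 0.04, each below the wild-type mean in 6 of 6 transgenic arrays. The camera p was 2.43e-18 at the preset correlation and 0.0055 with an estimated correlation. The median was -0.102 on day 1 and -0.132 on day 2, -0.13 within the larger chip lot, -0.099 with equalized array medians, -0.11 after repeated quantile normalization and -0.0931 with the slow-fibre covariate. Lower ribosomal protein transcripts in transgenic muscle may thus be a hypothesis to test in other samples, as these values cannot test it independently.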
